A study of Drosophila melanogaster with 3 samples.

How the data were processed

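Su(var)3-7-GFP ChIP-seq of whole embryos was represented by 3 biological replicates in 1 group, numbered as in the labels. Per the deposited inventory texts, relaxed regions ("peaks and background") were listed by the authors for each replicate from its alignments and 1 control file, and for the 3 replicates pooled with 1 control file; a thresholded set was then derived from the pooled and replicate lists by the irreproducible discovery rate. The aligner, the peak caller, the threshold, read filters and versions are not given in the sources used here. Each list was deposited on dm6 and dm3. Signal values are the deposited ones that the authors' caller gave each region, on a scale that is not stated; they served to rank and describe regions within a list, and between replicates only as ranks or after division by the list's median. Read depth is unknown, so no interval that needs it is given; intervals on shares cover counting of regions only. The control reads and any untagged or mock precipitation were not analysed here.

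Coordinates were used on dm6, whose chromosome lengths contained every summit of the dm6 lists, and are given 1-based. Protein-coding start sites (19630, for 13968 genes) came from Ensembl release 115 of BDGP6.54, and 5734 mobile elements and masked bases from the RefSeq annotation and genome. Of the 30000 pooled regions, 25047 overlapped no thresholded peak by 1 bp or more and served as background; 898 further regions overlapped a thresholded peak and were left out. The thresholded list held 17 repeated intervals with different summits, and each summit was kept. A summit was at a start site within 500 bp of it. Pericentric sequence was taken as 2L from 22 Mb, 2R to 5.7 Mb, 3L from 23 Mb, 3R to 4.2 Mb and X from 22 Mb. A replicate's own value came from its strongest 4055 regions, against its regions that overlapped none of those. Shares were compared by two-sided Fisher's exact tests, with log2 odds ratios and 95% Wald intervals, 0.5 being added to each cell where a count was 0; no odds ratio is given for chromosome Y. These tests treat regions as independent, which neighbouring peaks are not, and have no replicate term; means and SDs over the 3 replicates stand beside them. A single group allows no test between groups.

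The 16 gene lists and 24 motifs, the pericentric boundaries, the tests and most alternatives were fixed before the data were examined. A gene counted as bound with a summit within 500 bp of any of its start sites, so a peak between close neighbours counts for both. Motifs were searched on both strands within 100 bp of each summit and in an equal window 1 kb to a side drawn at random (seed 1), and compared by exact McNemar tests. P-values were adjusted by Benjamini-Hochberg over arms, annotation classes, lists or motifs, with 0.05 as the threshold. Median signals were compared by 100000 permutations of peaks. Genes were named by a fixed rule: the gene with the nearest start site within 500 bp of each of the 20 strongest peaks, Su(var)3-7, and of each list up to 4 members with the strongest start-site peak and the first 2 in alphabetical order without one; the 10 strongest distal peaks were named by position. Haspin, the peaks inside AGO3 and Dbp80, and the peaks and genes named only in the closing section, were chosen after their values were seen.

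Alternatives were the 2027 strongest thresholded peaks, regions among the strongest of all 3 replicates (2473) or of each pair (2828 to 2966), a weaker background, other windows, distances and boundaries, and dm3 lists for counts by chromosome. In a simulated peak set of the size of the thresholded dm6 set, 100% of 2027 summits placed on start sites were recovered, which their placement fixed. For the lists, genes drawn at random were taken as bound, each at 1 start site without a window. They gave 0.08 calls per draw over the 16 lists. The ribosomal protein list, with 40% of its members added as bound, was called in 100 of 100 draws. Recovery of the other lists, and peaks shared by close neighbours, were not simulated. None of 24 motifs was called at random positions, and a planted motif was called. On smaller groups of values, 5 of 100 permutation tests without a difference fell under 0.05. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9. The replicates' dm3 lists were not used here.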

Results

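The binding of Su(var)3-7, a zinc-finger protein of fruit fly heterochromatin whose gene was named for its effect on position-effect variegation, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole Drosophila melanogaster embryos. The flies carried a transgene for Su(var)3-7 fused to green fluorescent protein (GFP), and chromatin from mixed-sex embryos aged 0 to 24 h was sheared by sonication and precipitated with an antibody against GFP. The labels give 1 group of 3 biological replicates. The data were peak lists: 30000 relaxed regions for each replicate, 30000 for the replicates pooled, and 4055 peaks that passed the authors' reproducibility threshold on genome build dm6. These 4055 peaks were the 4055 strongest of the pooled list, 13.5% of it, with a median width of 424 bp. Their signal values, the authors' own, ran from 119 to 3827 with a median of 181, against 52.9 for the whole pooled list. The lists gave no read counts, so the depth of each replicate is unknown. With a single group, the comparisons were between the thresholded peaks and the 25047 weaker regions of the pooled list that overlapped none of them, and between replicates.

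The first question was how far the replicates agreed. The strongest peak, inside an intron of ush, stood at 59.6 ± 11.1 times the median signal of each replicate's list (SD, n = 3), and the peak at the start site of Ugalt, which encodes a UDP-galactose transporter, at 56.5 ± 6.89 times. Across peaks, Spearman's rank correlation of signal was 0.738 between replicates 1 and 2, 0.716 between 1 and 3, and 0.729 between 2 and 3; peaks are not independent replicates, so no test was made. Of the 4055 strongest regions of a replicate, 71.4% ± 1.53 (SD, n = 3 pairs of replicates) had a summit within 200 bp of one of another replicate's strongest, against 14.4% to 14.5% for regions drawn at random from its list. Of the thresholded peaks, 2456 (60.6%) were among the strongest regions of all 3 replicates, 1079 (26.6%) of 2, 496 (12.2%) of 1 and 24 (0.592%) of none. Each replicate list was called with its own reads, so a peak ranked just below the strongest 4055 counts as absent here.

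The strongest peaks lay at start sites and in introns along the chromosome arms. Of the 20 strongest peaks, 12 had a summit within 500 bp of a protein-coding start site. In order of signal these belonged to Ugalt, CG14100, px, mRpL41 (a mitochondrial ribosomal protein), Chro (the chromodomain protein Chromator), ph-p (a Polycomb group protein), PNPase (a mitochondrial RNA-degrading enzyme), Art3 (an arginine methyltransferase), CG1888, Shc (a signalling adaptor), larp (an RNA-binding protein) and CenG1A. The Ugalt peak spanned X, 2703651 to 2704110, with a signal of 3571, and its summit was 39 bp from the start site. The Chro peak spanned 3L, 22878696 to 22879126, with a signal of 2117, or 32.9 ± 6.41 times the list median (n = 3). The Art3 peak (3R, 15229319 to 15229740, signal 2016) also lay within 500 bp of the start site of mRpS10, and the CenG1A peak (2L, 13835269 to 13835652, signal 1696) within 500 bp of that of mRpS23. The other 8 of the 20 lay away from start sites: 5 in introns, 1 in a non-coding gene and 2 between genes.

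Distal peaks were led by 1 in an intron of ush, which encodes a Friend-of-GATA zinc-finger protein, at 2L, 480589 to 481333, with a signal of 3827; its nearest start site was that of cbt, 1397 bp away. Next were intronic peaks in CG11050 (2L, 6612486 to 6612929, signal 2690) and in the kinase gene Lk6 (3R, 11760820 to 11761335, signal 2455). A peak of signal 2106 lay in the non-coding gene lncRNA:Vinr (X, 12751119 to 12751639), and another of 1556 about 1 kb further on, in lncRNA:CR44619 (X, 12752158 to 12752551). Intronic peaks in CG9663 (2L, 3301938 to 3302428, signal 1909) and CG32772 (X, 4910191 to 4910587, signal 1722), and a peak in lncRNA:CR31840 (2L, 14023901 to 14024322, signal 1465), were also among the 10 strongest distal peaks. The 2 intergenic peaks of this group lay 3169 bp from the start site of tara (3R, 16222262 to 16222704, signal 1782) and 11957 bp from that of CG13323 (2R, 13035132 to 13035541, signal 1723). The gene of the tagged protein carried a peak of its own: the Su(var)3-7 peak (3R, 13264038 to 13264461) had its summit 114 bp upstream of the start site, a signal of 222 and rank 1430, at 3.62 ± 0.923 times the list median (SD, n = 3).

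Su(var)3-7-GFP peaks were concentrated at the start sites of protein-coding genes and nearly missing from coding exons away from start sites. Of the thresholded peaks, 2089 (51.5%) had a summit within 500 bp of a start site, against 24.7% of the weaker regions (log2 odds ratio 1.70, 95% interval 1.60 to 1.80; two-sided Fisher's exact test, p = 3.74e-248). The strongest 4055 regions of each replicate gave 51.3% ± 1.60 and the rest of its list 23.9% ± 1.05 (SD, n = 3), so the difference was far larger than the spread between replicates. Summits sat mostly just upstream: 1621 (77.6%) of the 2089 lay before the nearest start site, at a median offset of -69 bp, and 1606 (76.9%) lay within 200 bp of it. Away from start sites, 1292 peaks (31.9%) were in introns and 497 (12.3%) between genes, against 33.9% and 15.04% of the weaker regions. Coding exons away from start sites held 29 peaks (0.715%) but 19.7% of the weaker regions (log2 odds ratio -5.09, interval -5.61 to -4.56; Fisher's exact test, Benjamini-Hochberg adjusted p = 2.29e-300 over 6 classes). Each summit had 1 class, with start sites taken first, so coding exon summits within 500 bp of a start site are not counted here. In the replicates the coding exon share was 1.35% ± 0.835 of the strongest regions and 19.8% ± 1.85 of the rest (SD, n = 3). Both sets come from the ranked list of the same libraries, so these shares compare strong with weak regions, and neighbouring peaks are not independent.

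**Figure D1:**
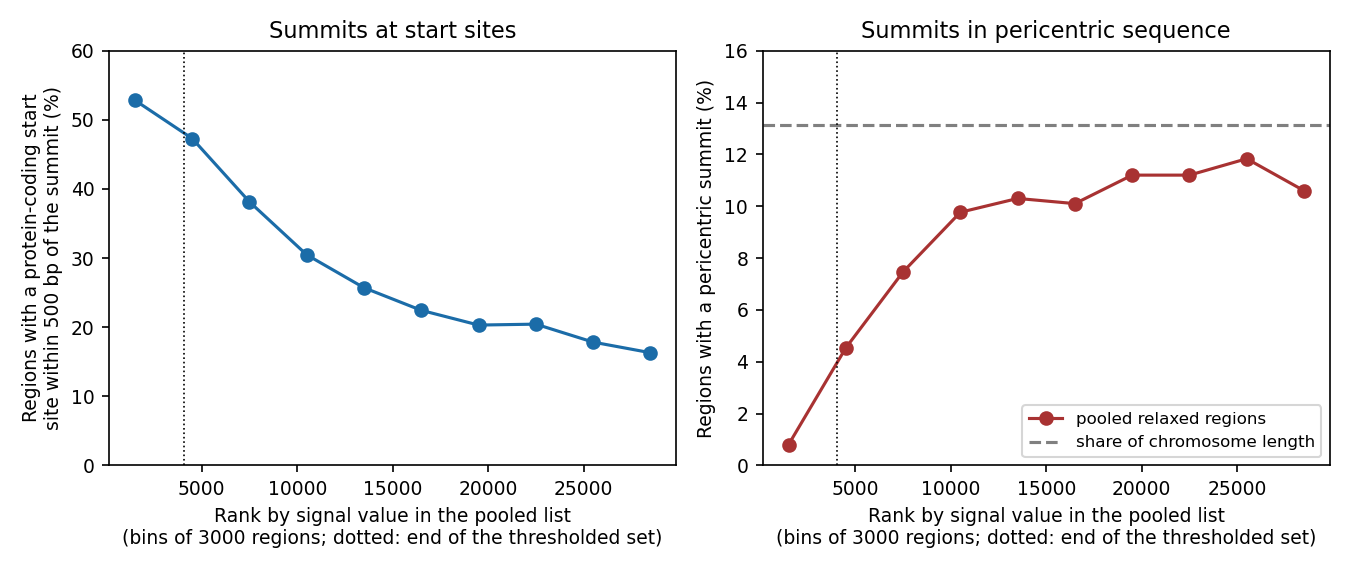
Share of the 30000 pooled relaxed regions with a summit within 500 bp of a protein-coding start site (left, %) and in pericentric sequence (right, %), by rank of signal in bins of 3000 regions; the dotted line ends the thresholded set and the dashed line is the pericentric share of chromosome length. The start-site share went from 52.8% in the strongest bin to 16.3% in the weakest, and the pericentric share from 0.8% to 10.6%.

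Thresholded peaks were scarce in pericentric heterochromatin, the repeat-rich sequence beside the centromeres where this protein is known to reside. Only 63 (1.55%) of them had a pericentric summit, against 2541 (10.1%) of the weaker regions (log2 odds ratio -2.84, 95% interval -3.20 to -2.47; two-sided Fisher's exact test, p = 1.93e-98). The 18.1 Mb counted as pericentric made up 13.1% of the chromosome arms. Pericentric regions were 2.34%, 1.13% and 3.63% of the strongest regions of replicates 1, 2 and 3 (mean 2.37% ± 1.25, SD, n = 3), and 9.42% ± 1.09 of the rest, so the deficit held in each. The pericentric peaks were also weak: 5 of the 63 were among the 2027 strongest peaks, and the highest signal was 243, at 2R, 4012718 to 4012887, with Haspin as the gene of the nearest start site. Among the 23 genes listed in advance as residents of heterochromatin, RpL15 alone carried a start-site peak (3L, 27266999 to 27267422, signal 126, 2.03 ± 0.105 times the list median, n = 3). AGO3 and Dbp80, also on that list, carried none at a start site, with relaxed regions of signal 35.8 and 74.5 there. Each did hold a thresholded peak of signal 143 far inside the gene (3L, 23580520 to 23580943, and 3L, 27323186 to 27323609). The boundaries were round approximations, and how reads from repeated sequence were handled is not given in the sources used here.

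Chromosome 4, a small and largely heterochromatic chromosome, held fewer peaks than its share of weaker regions. It carried 19 peaks (0.469%) against 1.31% of the weaker regions (log2 odds ratio -1.50, interval -2.16 to -0.83; Fisher's exact test, adjusted p = 3.34e-06 over 7 arms), or 14.1 peaks per Mb, where the arms 2L, 2R, 3L, 3R and X held 28.4 to 31.8. In the replicates its share was 0.436% ± 0.0142 of the strongest regions and 1.27% ± 0.151 of the rest (SD, n = 3). The larger arms differed little: 3R (log2 odds ratio 0.28, adjusted p = 1.11e-05) and 2L (0.15, 0.0223) held more peaks than their share of weaker regions, 2R (-0.22, 4.80e-04) and 3L (-0.23, 4.22e-04) fewer by the same exact test, and X (0.12, 0.0745) did not pass. Chromosome Y held 0 of the 4055 peaks (95% upper limit 0.0946%) and 1 weaker region. Against random positions in place of the weaker regions, chromosome 4 stayed lower (log2 odds ratio -1.02). There 2L, 2R, 3L and 3R no longer passed, and the values of 3R (-0.0046) and 2R (0.12) changed sign. On dm3, 2R and 3L did not pass either (adjusted p = 0.0814 and 0.15, exact test).

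Annotated mobile elements held 21 peak summits (0.518%), against 2.37% of the weaker regions (log2 odds ratio -2.22, interval -2.85 to -1.59; two-sided Fisher's exact test, p = 1.21e-18). In the replicates they held 0.756% ± 0.340 of the strongest regions and 2.34% ± 0.148 of the rest (SD, n = 3). Outside pericentric sequence the deficit was smaller (log2 odds ratio -1.33, exact p = 0.0037). Bases masked as repeats, which also include simple sequence runs, went the other way: 706 summits (17.4%) lay on them, against 13.4% of the weaker regions (log2 odds ratio 0.44, exact p = 4.94e-11), so the direction depends on what is counted as a repeat. Handling of reads from repeated sequence is not given in the sources used here. Loss of such reads in mobile elements therefore cannot be told apart from less binding.

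Genes for cytoplasmic ribosomal proteins, which make up the ribosome's protein part, carried Su(var)3-7-GFP peaks far more often than other genes. Of 93 such genes, 65 (69.9%, 95% Wilson interval 59.9 to 78.3) had a thresholded summit within 500 bp of a start site, against 18.1% of other protein-coding genes (log2 odds ratio 3.39; Fisher's exact test, Benjamini-Hochberg adjusted p = 3.04e-26 over 16 lists). The replicates gave 69.2% ± 2.24 (SD, n = 3). The strongest were at RpL7 (2L, 10200869 to 10201197, signal 1000.4, 15.9 ± 0.664 times the list median), RpL23A (3L, 1668580 to 1668914, signal 896), RpS27 (3R, 25247359 to 25247739, signal 886, 14.2 ± 0.297 times) and RpL41 (2R, 24903848 to 24904196, signal 775), with n = 3 for each mean. RpL10, in pericentric 3L, had only a relaxed region of signal 97.2, and RpL10Aa had none. In all, 2577 of 13968 protein-coding genes (18.4%) carried a start-site peak.

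Genes for insulator and chromosome architecture proteins, which mark domain borders and organise chromosomes, formed the second group. Of 16, 9 (56.3%, interval 33.2 to 76.9) carried a peak (log2 odds ratio 2.51; Fisher's exact test, adjusted p = 0.00424), and the replicates gave 50% ± 6.25 (n = 3). Besides Chro, they included Trl, the gene of GAGA factor (3L, 14757072 to 14757333, signal 542), Dref, the gene of the DRE-binding factor (2L, 9967145 to 9967392, signal 415), and Cp190 (3R, 15275199 to 15275401, signal 346). Ibf1 had a weak relaxed region (signal 43.1) and Ibf2 none. This call was lost among the 2027 strongest peaks (exact test, adjusted p = 0.142) and when only genes with a relaxed region were counted (0.135), though the log2 odds ratio was still 2.02 and 2.03.

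The remaining calls above background were weaker. Mitochondrial ribosomal protein genes carried peaks in 26 of 73 cases (35.6%; Fisher's exact test, adjusted p = 0.00342; replicates 30.6% ± 4.40, n = 3), led by mRpL41 (2R, 15217570 to 15218017, signal 2155), mRpS10, mRpS23 and mRpL23 (3L, 2373426 to 2373813, signal 955); mRpL10 and mRpL12 had none. In replicates 1, 2 and 3, 21, 20 and 26 of the 73 carried a peak (adjusted p = 0.136, 0.134 and 0.00538, exact test), so the list passed in replicate 3 alone. Giving each peak only to its nearest gene left 13 of 73 (17.8%; log2 odds ratio 0.46 against 1.30 in full; adjusted p = 0.617, exact test), and the call was also lost without replicate 1 (0.145) and without replicate 3 (0.38), in 6 of 9 alternative settings. Replication and cell cycle genes (12 of 32, 37.5%; replicates 35.4% ± 9.02, n = 3), with dup, dpa, aurA and polo strongest at signals of 380, 358, 244 and 192, and core promoter factor genes (7 of 15, 46.7%; replicates 42.2% ± 7.70, n = 3), with Bdp1, Brf, Taf4 and TfIIA-S at 869, 541, 404 and 346, each had an adjusted p of 0.0371 by the exact test. CycE, E2f1, Gnf1 and Polr2A carried no peak. Both calls were lost in 8 of 9 alternative settings, among them leaving out any of the 3 replicates. Without replicate 1 the log2 odds ratios were 1.30 and 2.07, against 1.41 and 1.95 in full, so there the excess was of similar size. Without replicate 2 they fell to 0.79 and 1.16, and without replicate 3 to 0.81 and 1.18. Giving each peak only to its nearest gene left 9 of 32 replication genes (log2 odds ratio 1.32) and 3 of 15 core promoter factor genes (0.67). Over all alternatives the log2 odds ratios were 0.44 to 1.49 and 0.67 to 2.07.

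**Figure D2:**
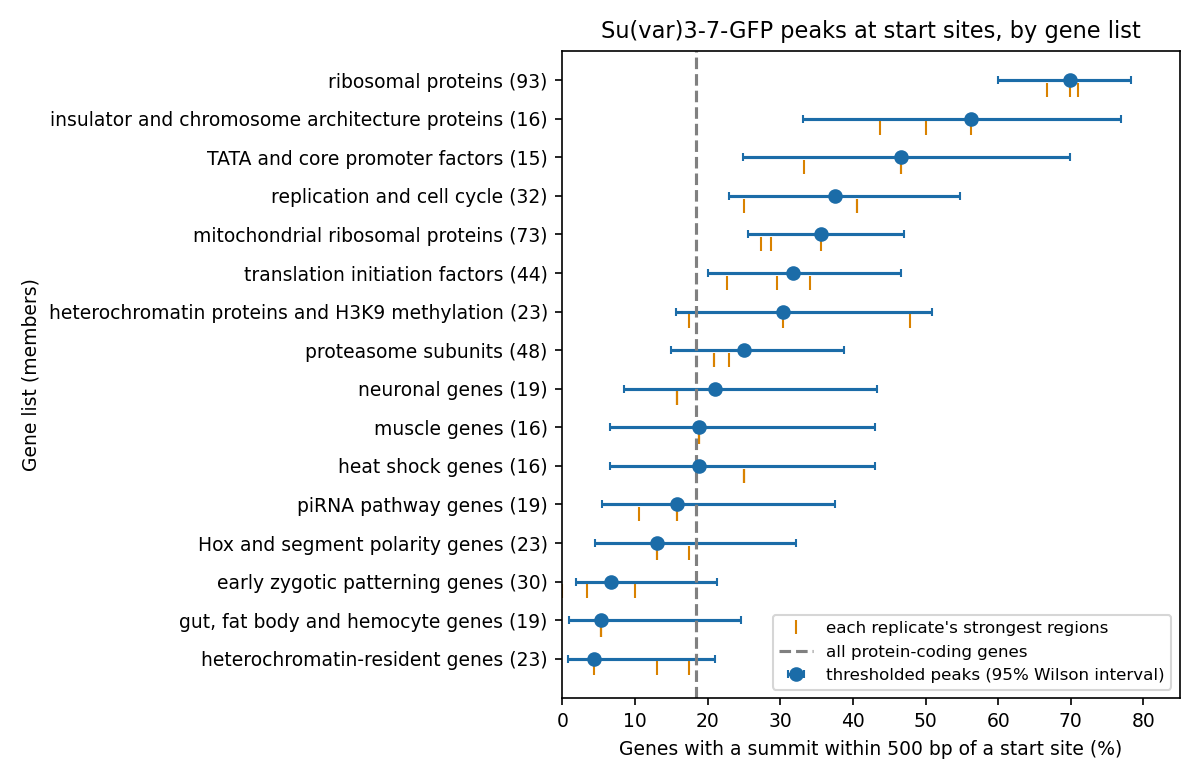
Share of the genes of each list with a thresholded summit within 500 bp of a start site (points, %, with 95% Wilson intervals), the same share from each replicate's strongest regions (ticks, which coincide where replicates tie), and the share of all protein-coding genes (dashed, 18.4%). Ribosomal protein genes, at 69.9%, stand highest.

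The other 11 lists did not pass. Genes of heterochromatin proteins and H3K9 methylation carried peaks in 7 of 23 cases (30.4%; adjusted p = 0.306, Fisher's exact test), with wide replicate spread (31.9% ± 15.3, n = 3). The list passed in replicate 3 alone (11 of 23; adjusted p = 0.00674, exact test), while replicate 2 had 4 of 23. Su(var)3-7, SuUR (signal 214), HP4 (179) and sov (176) were strongest, and ADD1 and HP1b had none. HP1b had a relaxed region of signal 117, just under the lowest thresholded signal. Translation initiation factor genes reached 14 of 44 (31.8%; adjusted p = 0.0816, exact test; 0.0432 with a start-site window of 200 bp), led by eIF6 (2R, 23850221 to 23850580, signal 1287), eIF3h (447), eIF2A (412) and eIF1 (352), without eIF1A (a relaxed region of signal 117) and eIF2Balpha. Proteasome genes reached 12 of 48 (25%), with Rpn5, Rpn13, Rpn6 and Rpn3 strongest at signals of 405, 256, 235 and 216, and neither Prosalpha1 nor Prosalpha1R. Neuronal genes had 4 of 19 (21.1%): elav (552), Nrx-1 (479), pros (131) and Syx1A (122), and not Gad1 or Rdl. Muscle genes had 3 of 16 (18.8%): Msp300 (751), sls (397) and Mef2 (152), and not Act57B or Act79B. Heat shock genes had 3 of 16 (18.8%): Hsp83 (510.2), Hsp27 (409) and Hsp26 (354), and not DnaJ-1 or Hsc70-4 (a relaxed region of signal 117).

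The lists with the lowest shares did not pass either. Hox and segment polarity genes had 3 of 23 (13.04%; adjusted p = 0.969, Fisher's exact test): eyg (signal 215), Dll (130.0) and ptc (126), and not Abd-B or Antp. Early zygotic patterning genes had 2 of 30 (6.67%; adjusted p = 0.305, exact test): rho (153) and btd (124), and not Kr or bnk. The replicates had 3, 1 and 0 of 30, and the list passed on the low side in replicate 3 alone (adjusted p = 0.014, exact test). Gut, fat body and hemocyte genes had 1 of 19 (5.26%; adjusted p = 0.37, exact test), fkh (601), and not Fbp1 or GATAd. Genes of the piRNA pathway, which silences transposons in the germ line, had 3 of 19 (15.8%): tud (185), cuff (179) and tej (163), and not AGO3 or Panx. Heterochromatin-resident genes had 1 of 23 (4.35%; adjusted p = 0.238, exact test; replicates 11.6% ± 6.64, n = 3). Lists of 15 to 30 genes give wide intervals.

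Of the 24 motifs, 8 were more frequent at summits than beside them, most of them through start-site peaks. The DRE element (TATCGATA), bound by DREF and BEAF-32, lay within 100 bp of 197 summits (4.86%) against 29 windows 1 kb away (0.715%), a ratio of 6.79 (two-sided exact McNemar test, Benjamini-Hochberg adjusted p = 7.49e-31 over 24 motifs). It was a start-site motif, in 9.05% of start-site peaks and 0.407% of distal peaks, and so was Motif 1 (GGTCACACT), bound by M1BP, in 4.40% and 0.254%, or 2.39% of all summits against 0.444% (exact test, adjusted p = 1.12e-13). The CTCF core (AGRKGGCGC), from the insulator protein CTCF, was in 2.74% of summits against 0.493% (ratio 5.55; exact test, adjusted p = 5.46e-16), and in 3.41% of distal peaks against 0.356% of their control windows. Ohler motif 7 (7.55% against 2.76%), Ohler motif 6 (7.62% against 3.58%), the Ohler E-box (4.14% against 1.53%) and the CGATA core of BEAF-32 (31.5% against 21.4%) were also more frequent at summits, with adjusted p of 1.74e-12 or lower by the exact test. At start-site peaks, motif 7, the E-box and CGATA reached 11.8%, 6.51% and 40.5%. At distal peaks they were in 3.05%, 1.63% and 22.02%, close to the 2.65%, 1.17% and 20.5% of distal control windows. Motif 6 was in 6.97% of distal peaks against 4.43% of their control windows, so its excess was not confined to start sites. The windows were not matched for base composition: mean GC content was 38.3% at distal summits and 41.3% in their control windows. The excess of AT-rich motifs such as motif 6 was not separated from this. The replicates gave 4.49% ± 0.261 for DRE, 1.965% ± 0.151 for Motif 1 and 2.44% ± 0.315 for the CTCF core (SD, n = 3).

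The TATA box (3.92% against 2.47%; exact test, adjusted p = 7.96e-04) completed the 8 motifs called, all of them more frequent at summits. At distal peaks the TATA box was in 3.81%, against 2.59% of their control windows. For this AT-rich motif too, base composition was not matched. Its call was lost in 4 of 8 alternatives: without replicate 1 (adjusted p = 0.226, exact McNemar test), without replicate 2 (0.138), among the 2027 strongest peaks (0.0623) and for regions strongest in all 3 replicates (0.0909). In that order its log2 ratio was 0.34, 0.42, 0.56 and 0.51, against 0.67 in full. The lowest adjusted p of the alternatives, 2.44e-06, came with weaker regions as controls. In that setting an equal number of weaker regions was drawn at random and compared, unpaired, by Fisher's exact test. Units of the simple satellites that fill fly heterochromatin were rare, and none passed: AAGAG repeats were in 5 summit and 5 control windows, AACAC repeats in 4 and 6, the dodeca core in 5 and 5, and AATAT repeats in 17 and 9 (adjusted p = 0.289, exact test). AATAT repeats did pass, in excess at summits, in windows of 50 bp each side (adjusted p = 0.00521, exact test) and with weaker regions as controls (0.0366), so their excess depended on the setting. All these windows lay at listed regions or 1 kb from them. The counts therefore cannot tell whether satellites outside the listed regions are bound. The GAGA element, the su(Hw), Pho and pita cores, the initiator, the Zelda element, GATA, Pangolin/TCF, AP-1 and heat shock elements, poly(A) runs and CA repeats did not pass. Windows of 200 bp each side, or weaker regions as controls, each called 13 motifs in place of 8. The weaker regions had a mean GC content of 46.2%, against 39.0% at thresholded summits, which was not adjusted for. Both settings added the GAGA element (adjusted p = 3.02e-14 and 0.0322, exact test), the su(Hw) core and the initiator. The wider windows also added the pita core and the Zelda element, the latter less frequent at summits, and the weaker regions added GATA and AATAT. The su(Hw) core passed in 4 of 8 alternatives, and CA repeats, less frequent at summits, in 3.

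**Figure D3:**
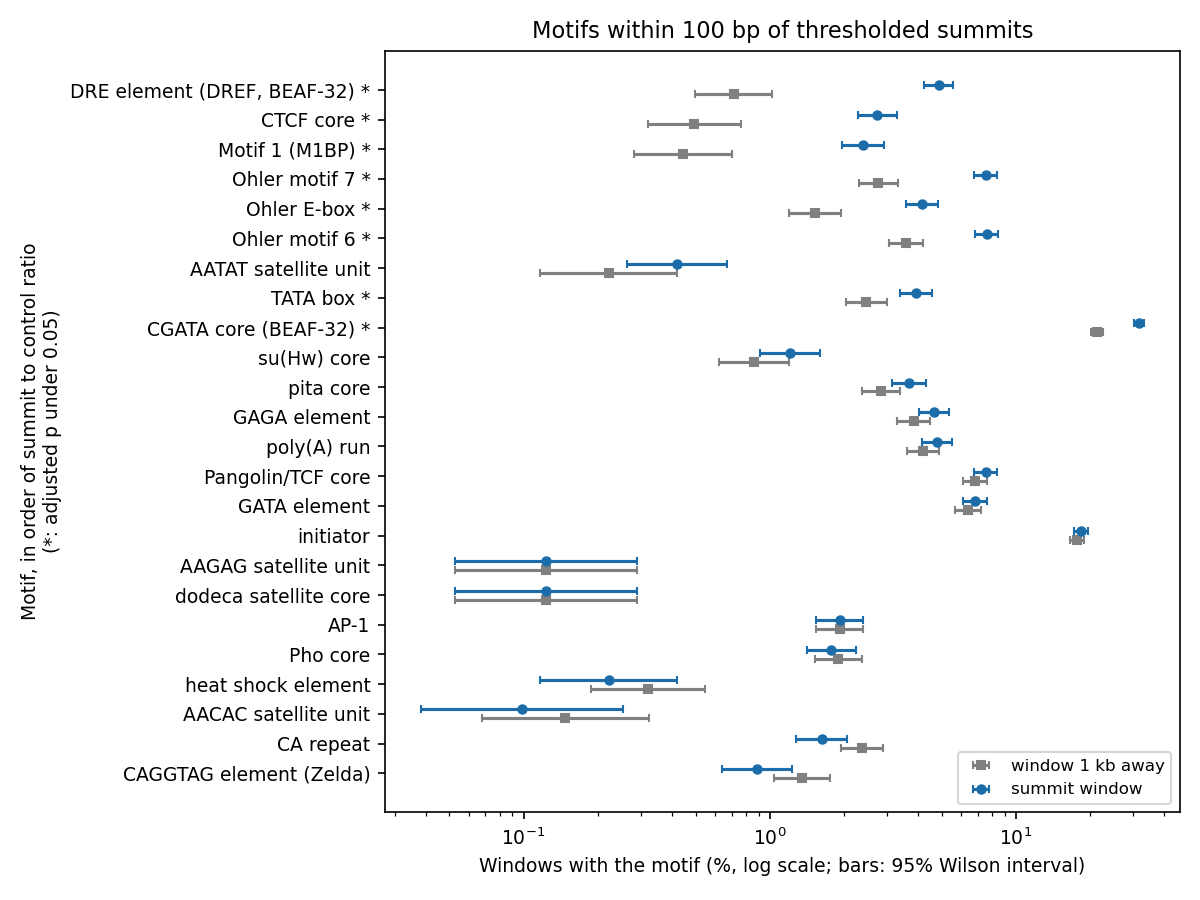
Share of windows with each motif (%, log axis, 95% Wilson intervals) within 100 bp of the 4055 thresholded summits (circles) and in equal windows 1 kb away (squares), ordered by their ratio; stars mark adjusted p under 0.05. The DRE element stands at 4.86% against 0.715%, while AAGAG and dodeca satellite units have equal shares, on 5 windows of each kind.

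Summits were AT-rich in both classes of peak. Within 100 bp of thresholded summits the mean GC content was 39.0% (SD 7.24 over 4055 windows), against 43.1% in windows 1 kb away, 46.2% at the weaker regions and 42.2% over the arms without Y. The strongest regions of the replicates gave 39.6% ± 0.721 (SD, n = 3). Distal peaks were lower than their control windows by a mean difference of -3.004 percentage points (SE 0.237) and start-site peaks by -5.13 (SE 0.273). In 50 bp steps, GC content at distal summits fell to 36.2% between shoulders of 43.3% and 43.9% 200 bp to either side.

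**Figure D4:**
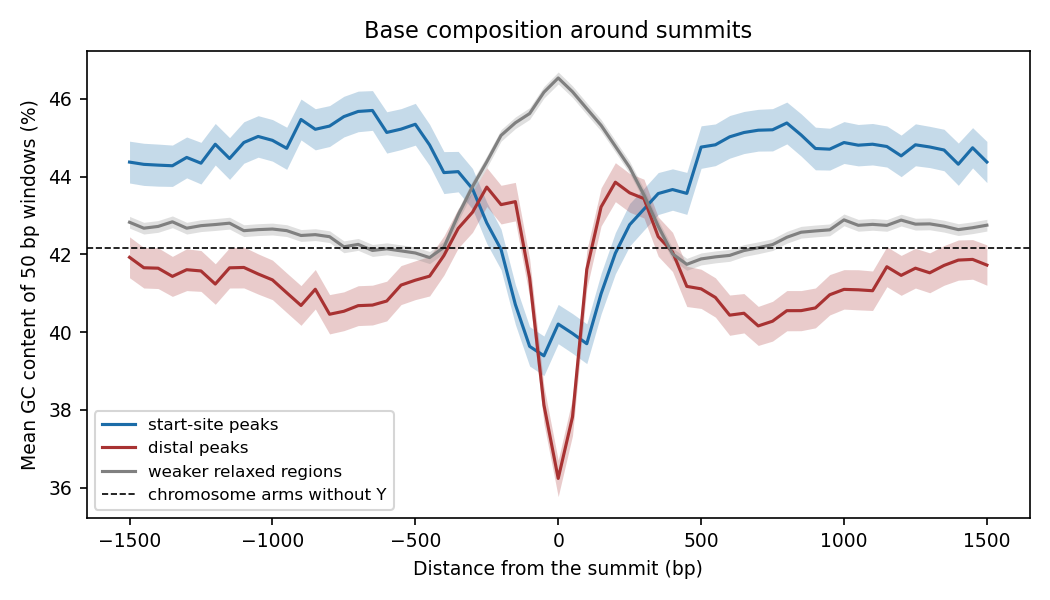
Mean GC content (%) of 50 bp windows by distance from the summit (bp) for start-site peaks, distal peaks and weaker relaxed regions, with bands for the 95% interval of the mean; the dashed line is the chromosome arms without Y. Distal peaks dip to 36.2% at the summit, where the weaker regions reach 46.5%.

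Start-site and distal peaks were of similar strength. The median signal was 184 at the 2089 start-site peaks and 177 at the 1966 distal peaks, a ratio of 1.04 (two-sided permutation test across peaks, p = 0.032). The ratio was 1.10, 1.00 and 1.09 in replicates 1, 2 and 3 (mean 1.07 ± 0.0578, SD, n = 3), so the difference was about as large as the spread between replicates and was missing from replicate 2. Regions shared by replicates carried the signal of the lowest-numbered replicate only. The permutation p was 0.449 for regions shared by replicates 2 and 3, with the signal of replicate 2. With the signal of replicate 1 it was 0.0565 for those shared by replicates 1 and 3. It stayed under 0.05, again with that signal, for regions shared by replicates 1 and 2 (1.30e-04) or strongest in all 3 replicates (0.0374). These p-values are therefore not independent of the ratios of replicates 1 and 2 above. Among the 2027 strongest peaks, with the authors' pooled signal, the permutation p was 0.0329.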

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

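The tests of AT-rich fragments over the whole library and of a single replicate setting the pericentric deficit were chosen after the results they bear on were seen. On dm3, which lists heterochromatic and unplaced sequences that the comparisons did not use, 9 of the 4112 thresholded peaks (0.219%, 95% Wilson interval 0.115 to 0.415) lay on them: 1 on 2RHet, 4 on 3LHet, 1 on 3RHet and 3 on Uextra. That share is above the 0.073% that a count of 0 allows, which shows only that some peaks were listed there. The share was 3.10% (931 regions) in the pooled dm3 list.

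Thresholded peaks were rare in pericentric heterochromatin, although Su(var)3-7 is known as a heterochromatin protein. Among summits on unmasked bases the log2 odds ratio was still -2.69 (interval -3.08 to -2.31). This cannot decide on read loss in repeats, since only the summit base had to be unmasked and repeats may lie around it. The pericentric share of the weaker regions was 10.1% with and without that filter. Among distal summits the log2 odds ratio was -2.45 (-2.86 to -2.04), which argues against a mere lack of start sites. The weakest deficit of the 3 replicates was -1.59, in replicate 3, with an interval of -1.83 to -1.34, so no single replicate set it. Sequence without listed regions stays open: the repeated histone gene cluster (2L, 21416953 to 21541681, 111 genes) held 0 thresholded and 0 relaxed regions, and binding in satellites or spread over broad domains may be missed in the same way. No biological explanation was tested, since the design has 1 group.

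Summits were AT-rich. A preference for AT-rich fragments over the whole library would lower listed regions of any strength. Over the 16194 pooled regions outside start sites and coding exons, strong and weak, GC content was 0.861 percentage points (SE 0.0859) above windows 1 kb away. The weaker regions, 25047 of the 30000 pooled, had already been seen at a mean of 46.2%. Such a value was therefore likely beforehand, and it does not decide the question. Position at start sites alone was not enough, since distal summits differed from their control windows by -3.004 percentage points (SE 0.237). A preference by the protein or its partners, or for nucleosome-free DNA, may remain as hypotheses; neither was tested, nor was a bias that acts on strong peaks alone.

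Ribosomal protein genes carried peaks in 69.9% of cases. Among genes without CGATA, and so without a DRE, within 500 bp of a start site, 7 of 10 ribosomal protein genes and 295 of 2531 others carried a peak. The odds ratio was 17.7 (95% interval 4.55 to 68.8), which argues against these elements as the cause at those 10 genes. It cannot decide on the 83 ribosomal protein genes with CGATA, a short word also present at 11344 other genes. High expression stays open: of 54 other genes known for abundant transcripts, 53.7% carried a peak, 16.2 percentage points below the ribosomal protein genes (two-sided Fisher's exact test, p = 0.0528), and well above other genes (log2 odds ratio 2.41, interval 1.63 to 3.18). Open chromatin at active promoters may therefore contribute through more efficient precipitation, and an untagged control would separate this from binding by Su(var)3-7; it was not analysed here.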

How the results depend on the processing

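Random positions as background, masked bases as repeats, mobile elements outside pericentric sequence and nearest genes only were added after seeing the data. The start-site excess (log2 odds ratio 1.35 to 3.09), the pericentric deficit (-5.51 to -2.30) and the deficit on chromosome 4 (-1.86 to -1.02) kept direction and significance in every alternative run, and so did mobile elements (-3.51 to -1.33) apart from masked bases, which reversed to 0.44. Random positions ended the calls of 2L (0.11), 2R (0.12), 3L (-0.066) and 3R (-0.0046), the values of 2R and 3R changing sign without passing. On dm3 the calls of 2R (-0.12) and 3L (-0.089) ended. X passed (0.18) for regions strongest in all 3 replicates. The weaker regions were unevenly spread over the arms; otherwise the cause was not tested.

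The 5 gene lists called became 1 among the 2027 strongest peaks, 2 for regions strongest in all 3 replicates, 2 to 3 without 1 replicate, 3 with a window of 1000 bp, 6 with one of 200 bp, 1 among genes with a relaxed region and 2 for nearest genes only. Ribosomal proteins were called in all 9 alternatives (log2 odds ratio 2.45 to 3.89), insulator proteins in 7. The list added at 200 bp was translation initiation factors (adjusted p = 0.0432, exact test). Smaller sets have fewer bound genes; otherwise the cause was not tested. Motif calls went from 8 to 13 with windows of 200 bp and 13 with weaker regions as controls, and 7 of the 8 motifs kept their call in all 8 alternatives. Of the motifs not called, GAGA, initiator and AATAT passed in 2 alternatives each, CA repeats in 3, su(Hw) in 4, and Zelda, pita and GATA in 1 each. The log2 ratio of start-site to distal signal was 0.024 to 0.11 without 1 replicate and of these passed only without replicate 3. It also passed among the 2027 strongest peaks (0.083, permutation test, p = 0.0329) and for regions strongest in all 3 replicates (0.073, p = 0.0374). Without replicate 1 the signals were those of replicate 2 alone. Without replicate 2 or 3, and for regions strongest in all 3, they were those of replicate 1 alone. Replicate sharing was 66.2% within 100 bp, 77.2% among the 2027 strongest and 69.9% to 72.9% without 1 replicate. The count of 4055 peaks was 4112 on dm3. Without read depth, weak peaks cannot be told from shallow sampling.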

Other observations

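The peaks listed by region in the first 2 paragraphs were chosen after the results were seen; the test of words was set before its outcome was seen, on a pattern found in these data, and the comparison of gene pairs after. On chromosome 4, 10 of the 19 peaks lay at start sites and 10 were among the 2027 strongest. The strongest was 19089 bp from the start site of lgs (424695 to 424955, signal 512), followed by peaks nearest to Cals (1113197 to 1113470, signal 499) and zfh2 (497793 to 497998, signal 381). The ribosomal protein gene RpS3A (signal 243) and the kinase gene CaMKII (signal 156) carried start-site peaks there. Of the 63 pericentric peaks, 12 (19.0%) were at start sites, among them those of IntS3 (2R, 4242871 to 4243294, signal 180.2) and beta-Man (3R, 4197105 to 4197528, signal 172), against 51.5% of all peaks.

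For genes of non-coding RNAs, a summit lay within 500 bp of the start of 21 of 290 tRNA genes (7.24%), 20 of 269 snoRNA genes (7.43%), 7 of 32 snRNA genes (21.9%, 95% Wilson interval 11.0 to 38.8) and 0 of 99 annotated rRNA genes, whose sequence is repeated. No test was made between these classes. Away from protein-coding start sites the shares were 5.04%, 5.42% and 20.7% for tRNA, snoRNA and snRNA genes.

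A family of 8-base words around CACTG may mark part of the summits. Among the 100 words most in excess at summits of 2L, 2R and X, 30 held CACTG or its complement, among them CAACACTG, CACTGTGC and CACTGAGA. On 3L, 3R and 4, which were not used to rank the words, the median ratio of summit to control share was 3.21, against chance in the ranking. The CACTG pattern itself was found in these data, so these arms may not be wholly independent of it. Any of the 30 words lay at 582 of these 1760 summits (33.1%) and in 212 control windows (12.0%; two-sided exact McNemar test, p = 2.63e-49), in 29.6% of start-site and 37.0% of distal peaks. Unlike DRE and Motif 1, the words were thus frequent at distal peaks too, though control windows were not counted by class. Whether Su(var)3-7 or another protein reads them was not tested.

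Divergent gene pairs, with head-to-head start sites within 1000 bp, may carry peaks more often than their number of start sites explains. Of 4965 such genes, 1557 (31.4%) carried a start-site peak, against 11.3% of other genes. Counting each pair once, at 1 start site, 715 of 2412 pairs (29.6%) carried a peak against 9.69% of single start sites. The bound set first, an odds ratio above 1, decided nothing, since the window of 1 start site can also hold its partner. If start sites were independent, 18.4% of pairs would carry a peak, and the observed share was 11.2 percentage points higher (95% interval 9.08 to 13.3), which argues against shared windows as the whole cause. The start site used for single genes, the farthest upstream, was chosen after a first run with the lowest coordinate (9.17%). Pairs included 56 of the 93 ribosomal protein genes, and expression was not measured here.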
